A study of Mus musculus with 14 samples.

How the data were processed

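Bulk RNA sequencing was done on c-KIT-positive spermatogonia sorted by flow cytometry from mouse testes, with 14 libraries in 4 groups. The deletion experiment has 2 control and 2 Cbx2-deleted libraries, and the 23KRA experiment 5 wild-type and 5 homozygous libraries. Deleted animals received 200 µL of tamoxifen at 20 mg/mL by 3 injections and their controls corn oil alone, per the labels' protocols. Deletion libraries were made with a SMART-Seq mRNA kit from 20 ng of RNA, with 7 cycles of cDNA amplification, 1.3 ng of cDNA and 11 library cycles, per the labels' protocols. The 23KRA libraries were made with a stranded total RNA kit with depletion of ribosomal cDNA, 5 cycles and then 16 cycles of PCR, per the labels' protocols, although the labels' molecule field gives polyA RNA for these libraries too. The kits differ, so the experiments were normalized and tested apart.

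The deposited values are raw counts of reads per gene, 24984 gene symbols in each of 2 tables, with no normalization. Reads were processed with Trim Galore 0.4.3, STAR 2.5.3, SAMtools 1.4.1, featureCounts and Subread 1.5.0 on mm10, per the submitters' processing notes. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Overlapping, antisense and near-identical genes may therefore share counts. No mitochondrially encoded gene was in the tables used here. Every column of counts was matched to its library by name. Positions of named genes are from GENCODE annotation of GRCm38, the assembly called mm10 elsewhere.

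All later steps used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15. Genes were kept by edgeR's filterByExpr, which left 16725 genes in the deletion and 14208 in the 23KRA experiment. Libraries were scaled by TMM factors, and CPM values use these scaled library sizes. Each comparison was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, with 2 residual degrees of freedom in the deletion and 8 in the 23KRA experiment before spread was shared across genes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The effects were compared by the interaction contrast in 1 fit of 4 group means. Gene lists were tested by camera with a preset correlation of 0.01 between genes where at least 3 members were tested, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also tests on the residual degrees of freedom, 2 in the deletion, so a list there could hardly pass. Summed CPM of each list was compared by an exact two-sided permutation test of log2 values. Depth differs between the experiments, and counting error is only part of the spread between libraries. Amplified reads are not independent molecules, and how much this adds was not measured.

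The groups, comparisons, tests, gene lists and most alternatives were chosen before the data were examined. There were 24 lists, of which 21 had enough tested members in each experiment; the mitochondrially encoded genes, mast cells and erythroid cells did not. Older symbols were matched through RefSeq synonyms. Named genes are Cbx2, then up to 10 risers and 10 fallers with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group, no overlap between groups and a symbol that is not a predicted model. Fewer than 5 genes passed in each comparison, so genes of smallest p that met the CPM and symbol conditions were added up to 10 and are said not to have passed. For each list, up to 4 members that passed are named, or else the 2 of highest mean CPM. Some members that this rule takes are not reported here. Members that passed only over their list alone (Insl3, Lhcgr and Scarb1) fall outside this rule and were chosen after their values were seen, as were Hsd3b6, Hsd3b1, Hsd17b3 and Cyp11a1. The sets of genes called in the deletion held fewer than 5 genes, so they were not tested in 23KRA, and the planned sets of 100 genes of smallest p in each direction were used.

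Before use, the test was run on counts simulated from each experiment's means, library sizes and gene dispersions, with 200 genes changed by 1.25, 1.5, 2 or 4 fold in each of 5 simulations. Of the calls, 4.39% were false in the simulated deletion (16526 genes tested) and 4.66% in the simulated 23KRA experiment (13739 genes tested). Simulated genes vary independently, so these simulations do not test the assumption camera makes about correlation. Alternatives were DESeq2 size factors, upper quartile scaling, no filter, a filter at 5 CPM, DESeq2, limma-voom, a replicate block, a minimum log2 fold change of 1 and leaving out each library. limma-voom with sample quality weights, and the 23KRA experiment without the 2 libraries with the fewest genes detected, were added after the data had been seen.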

Results

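c-KIT-positive differentiating spermatogonia, the male germ cells that have left the stem cell pool and are moving toward meiosis, were sorted from testes of C57BL/6J mice and profiled by bulk RNA sequencing in 2 experiments on Cbx2, a chromodomain subunit of the Polycomb repressive complex PRC1. In the deletion experiment, 2 animals with the genotype Rosa26-CreERT2; Cbx2 Flox/Δ had received tamoxifen, which activates the recombinase, and 2 animals with the genotype Rosa26-CreERT2; Cbx2 Flox/+ had received corn oil. The Rosa26 locus is active in most cell types, so this driver does not restrict recombination to germ cells. In the 23KRA experiment, 5 animals homozygous for an allele with lysine and arginine residues of the CaPS domain replaced by alanine were set against 5 wild-type animals. The labels count as many animals as libraries in each group, and each library was taken as 1 animal. The p-values therefore measure the spread between animals and their preparations together, and take the preparations as separate. The deletion libraries held 28169990 to 31166500 counts assigned to genes and detected 19822 to 19976 genes each. The 23KRA libraries held 14562564 to 19814511 counts and detected 14958 to 17330 genes. Replicates were closer in the deletion experiment, with a common biological coefficient of variation of 0.0988 against 0.393 in the 23KRA experiment. Within groups, the ratio of variance to mean for genes with 5 to 20 counts was 2.25 in the deletion libraries and 15.5 in the 23KRA libraries. Chi-square per degree of freedom between replicates of a group was 11.8 to 14.5 in the deletion and 14.5 to 43.5 in the 23KRA experiment, so no pair agreed within counting noise.

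**Figure D1:**
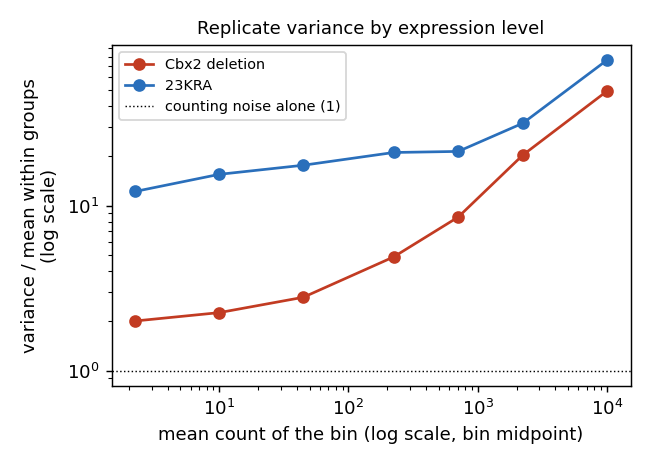
Ratio of variance to mean of the scaled counts within groups (vertical, log scale, no unit) against the mean count of each bin of genes (horizontal, log scale), for the deletion libraries in red and the 23KRA libraries in blue; the dotted line at 1 is counting noise alone. For genes of 5 to 20 counts the ratio is 2.25 in the deletion libraries and 15.5 in the 23KRA libraries.

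Cbx2 transcripts were still abundant in the animals labelled as deleted. Cbx2 (chromosome 11, 119022962 to 119031270 on the plus strand of GRCm38, a protein-coding gene) stood at 93.9 and 97.7 CPM (counts scaled to a common library size, as for all levels given) in control replicates 1 and 2 and at 78.5 and 86.5 CPM in deleted replicates 1 and 2. The mean was 95.8 ± 2.67 CPM (SD, n = 2) in controls and 82.5 ± 5.66 CPM (SD, n = 2) in deleted animals, 86.2% of the control level. The log2 fold change was -0.21 (SE 0.12; edgeR quasi-likelihood test, adjusted p = 0.971), and an exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, the value it gave. The counts cover the whole gene, and the labels do not say which exons the floxed interval holds, so this level does not measure how many cells had lost the interval. In the 23KRA experiment Cbx2 was at 73.0 ± 12.6 CPM in wild type and 64.1 ± 17.4 CPM in homozygotes (SD, n = 5 each; exact two-sided permutation p = 0.349, smallest possible 0.00794), a log2 fold change of -0.19 (SE 0.16). Wild-type replicates 1 to 5 had 81.0, 79.2, 83.6, 53.2 and 68.0 CPM, and homozygous replicates 1 to 5 had 89.7, 57.9, 73.9, 48.8 and 50.3 CPM.

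**Figure D2:**
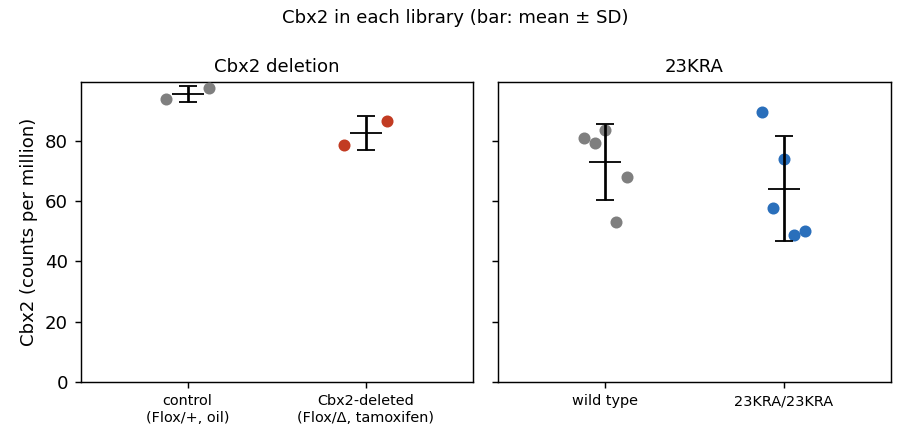
Cbx2 transcript level in CPM (vertical) in each library of the 2 experiments (points), with the group mean and SD (bars). Controls of the deletion experiment had 93.9 and 97.7 CPM and the deleted animals 78.5 and 86.5 CPM, while the 23KRA groups overlapped.

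The first comparison asked which genes differed between the deleted animals and their controls. Of 16725 genes tested, 1 rose and 1 fell, and both are genes of somatic testis cells. Cyp17a1, which encodes the 17-alpha-hydroxylase of androgen synthesis in Leydig cells, fell from 6.07 ± 1.84 to 1.66 ± 0.281 CPM (SD, n = 2 each), a log2 fold change of -1.86 (SE 0.26; edgeR adjusted p = 0.00315). Dcn, which encodes the connective tissue proteoglycan decorin, rose from 3.73 ± 1.19 to 11.0 ± 5.56 CPM (SD, n = 2 each), a log2 fold change of 1.57 (SE 0.26; edgeR adjusted p = 0.0207). Cyp17a1 lies on chromosome 19 at 46667165 to 46673172 (minus strand) and Dcn on chromosome 10 at 97479609 to 97518143 (plus strand, GRCm38). Cyp17a1 had 7.37 and 4.77 CPM in controls against 1.86 and 1.46 CPM in deleted animals. Dcn had 4.57 and 2.89 CPM in controls against 15.0 and 7.11 CPM in deleted animals. The next genes by p did not pass after adjustment and were also low in level. The tissue kallikreins Klk1b27 and Klk1 had log2 fold changes of 1.88 (SE 0.41) and 1.70 (SE 0.37), and Klk1 was at 0.882 ± 0.596 CPM in controls and 2.91 ± 0.709 CPM in deleted animals (SD, n = 2). They belong to a family of near-identical genes, and their counts are uncertain for that reason. Col3a1, a fibrillar collagen, had log2 fold change 2.22 (SE 0.48), the alcohol dehydrogenase Adh1 1.80 (SE 0.44) and the surface sialomucin Cd34 1.16 (SE 0.29). Values below 0 were seen for Bhmt, an enzyme of methionine metabolism (-2.38, SE 0.53), for angiotensinogen, Agt (-0.95, SE 0.21), and for Erdr1 (-0.78, SE 0.19). The smallest edgeR adjusted p among these 8 genes was 0.312.

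**Figure D3:**
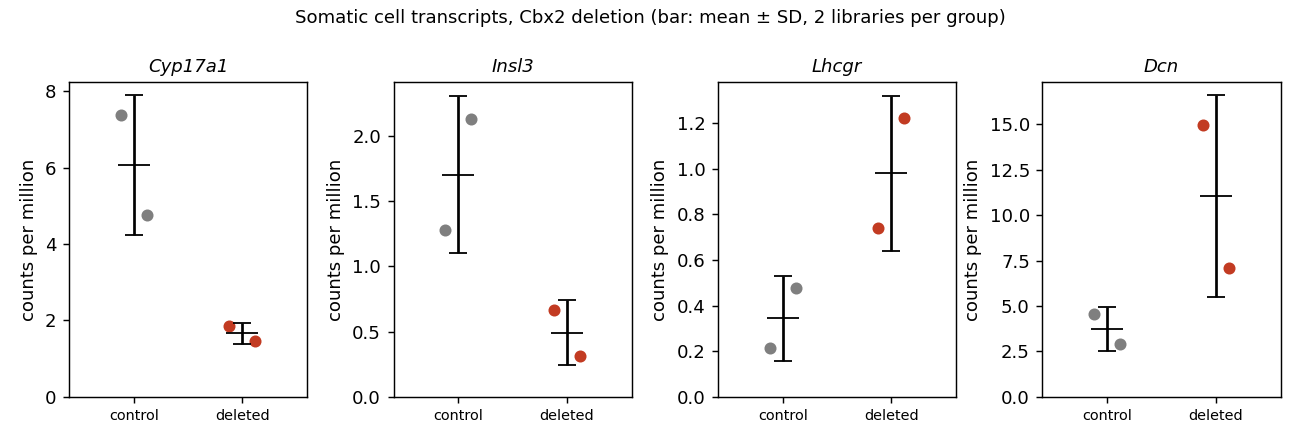
CPM (vertical, a separate scale per panel) of 3 Leydig cell genes and of Dcn in the 4 libraries of the deletion experiment (points), with group mean and SD (bars). Cyp17a1 and Insl3 are lower in both deleted libraries, and Lhcgr and Dcn are higher in both.

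The two-sided test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 793 genes had an unadjusted p under 0.05, where 836 were expected by chance. DESeq2 and limma-voom each called Cyp17a1 and not Dcn. The count of 2 genes was 11 without control replicate 1 and 73 without deleted replicate 2, and Dcn had a log2 fold change of 0.94 (edgeR adjusted p = 0.188) without deleted replicate 1. In counts simulated from these libraries, the test recovered 42.8% of 1.5-fold and 76.4% of 2-fold changes over all genes, and 66.0% and 100% among genes of at least 10 CPM, a level above that of Cyp17a1. Genotype and injection differed together between the groups.

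Among the gene lists fixed before the data were examined, those of Hox genes, other developmental transcription factors, Polycomb subunits and differentiating and undifferentiated spermatogonia did not pass after the deletion. Of 39 Hox genes, the classical targets of Polycomb repression, 19 had enough counts to test. None of these passed by itself, with 9 above 0 and 10 below (median log2 fold change -0.028, SD 0.55). Their summed level was 36.5 ± 1.31 CPM in controls and 34.8 ± 0.626 CPM in deleted animals (SD, n = 2), and the most abundant were Hoxd8, with a log2 fold change of -0.25 (SE 0.16), and Hoxa4 at 10.8 ± 0.0924 against 9.76 ± 0.937 CPM. The other Hox genes tested were at most 2.89 CPM in any library, where a change is hard to detect. None of 63 other developmental transcription factors passed (31 above 0, 32 below; median -0.0014, SD 0.44; median 0.18 without control replicate 2), and the most abundant of them were Tbx1 at 67.0 against 60.2 CPM and Lhx8 at 20.9 against 27.8 CPM. Subunits of PRC1 (22 genes, median -0.011) and PRC2 (13 genes, median -0.032) did not pass, with Scml2 at 524 against 563 CPM, Pcgf5 at 408 against 441 CPM, Rbbp4 at 791 against 810 CPM and Rbbp7 at 536 against 582 CPM. Of the markers of differentiating spermatogonia, 13 of 20 were above 0 and none passed (median 0.044). Stra8, which is also on the list of the retinoic acid response, had 536 ± 41.2 CPM in controls and 564 ± 45.1 CPM in deleted animals (SD, n = 2), and Nxf2 had 600 against 678 CPM. The 37 genes of undifferentiated spermatogonia had a median of 0.0019, with Uchl1 at 481 CPM in both groups and Taf4b at 371 against 398 CPM. Camera pointed up for the Hox genes and developmental transcription factors and down for the undifferentiated genes, against the sign of their medians, and passed in none of the 3 (adjusted p = 0.958, 0.821 and 0.985). With 1 library left out, the medians of the PRC1, PRC2, Hox and undifferentiated lists also changed sign, at most to 0.032, 0.032, 0.027 and -0.067.

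In limma's camera test of each list against all other genes, 5 of 21 lists passed in the deletion experiment. Spermatid transcripts, among them those of the sperm chromatin proteins protamine 1 and 2, were lower: all 24 had a log2 fold change below 0, with a median of -0.21 (camera adjusted p = 1.35e-11; adjusted p = 0.972 with an estimated correlation), and none passed by itself or adjusted over the list alone. Their summed level was 5797 ± 266 CPM in controls and 5080 ± 444 CPM in deleted animals (SD, n = 2), with Prm1 at 1101 against 979 CPM and Prm2 at 761 against 655 CPM. The Leydig list was lower (9 of 11 below 0, median -0.29; camera adjusted p = 0.00216; adjusted p = 0.972 with an estimated correlation). Adjusted over the list alone, Cyp17a1 and the peptide hormone gene Insl3 fell (log2 fold change -1.86 and -1.79) and Lhcgr, the luteinizing hormone receptor, rose (1.48, SE 0.53; edgeR adjusted p over the list alone = 0.0378), against 1 gene over all genes tested. The macrophage and leukocyte list was higher (14 of 16 above 0, median 0.34; camera adjusted p = 0.00432; adjusted p = 0.972 with an estimated correlation), with Cd74 at 17.0 ± 0.169 against 24.5 ± 13.4 CPM and H2-Ab1 at 28.5 ± 0.456 against 35.5 ± 12.6 CPM. Its summed level was 94.7 and 73.3 CPM in controls and 145 and 74.1 CPM in deleted replicates 1 and 2. Genes of the G2/M phase (24 of 30 above 0, median 0.050; camera adjusted p = 0.00743; adjusted p = 0.972 with an estimated correlation) and of meiotic prophase (27 of 37 above 0, median 0.065; camera adjusted p = 0.0339; adjusted p = 0.972 with an estimated correlation) were higher, with Top2a at 722 against 758 CPM, Cenpf at 536 against 540 CPM, Sycp1 at 1291 against 1358 CPM and Sycp3 at 1048 against 1193 CPM. None of the 5 lists passed with an estimated correlation, but that test has only 2 degrees of freedom here. For the Leydig list the estimated correlation was -0.093, below the preset 0.01, yet the unadjusted camera p rose from 2.05e-04 to 0.0601. Failing this test therefore does not by itself show that the calls came from correlation between genes. Without control replicate 2 the medians were -0.028 for macrophages, 0.019 for G2/M and 0.044 for meiotic prophase, none passed, and 2 lists were called in all. Without deleted replicate 1 they were -0.16, called as lower (camera adjusted p = 0.0121), 0.0066 and 0.047, the G2/M and meiotic calls were lost (camera adjusted p = 0.712 and 0.141), and the spermatid median was -0.12. Without deleted replicate 2 the meiotic call was lost (camera adjusted p = 0.0727, median 0.13), with medians of 0.15 for G2/M and 0.82 for macrophages. Without control replicate 1 the medians were 0.77 for macrophages, 0.11 for G2/M, 0.10 for meiotic prophase and -0.064 for Leydig cells, and without control replicate 2 the last was -0.50.

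The remaining lists did not pass in the deletion experiment. Their median log2 fold changes were 0.053 for 48 DNA replication genes (Mcm6 at 497 against 530 CPM, Rrm1 at 419 against 476 CPM), -0.12 for 8 CDK inhibitors (Cdkn3 at 87.3 against 82.2 CPM, Cdkn2d at 47.6 against 42.9 CPM; -0.057 without control replicate 1) and 0.060 for 27 p53 targets (Mdm2 at 220 against 240 CPM, Bax at 169 against 178 CPM). They were 0.055 for 15 genes of the retinoic acid response (Crabp1 at 212 against 220 CPM), -0.066 for 24 immediate-early genes (Jund at 240 against 242 CPM, Btg2 at 55.9 against 60.3 CPM) and -0.018 for 15 interferon response genes (Bst2 at 15.7 against 17.6 CPM). For 56 ribosomal protein genes the median was 0.039 (Rpl4 at 1044 against 1076 CPM). Markers of Sertoli cells (17 genes, median 0.090; Ctsl at 180 against 202 CPM, Clu at 86.1 against 83.0 CPM), peritubular myoid cells (9 genes, median -0.058; Actg2 at 52.3 against 50.2 CPM, Mylk at 15.8 against 13.9 CPM) and endothelial cells (9 genes, median 0.066; Egfl7 at 30.1 against 31.5 CPM, Vwf at 1.70 against 1.33 CPM) did not pass either. Camera pointed up for the interferon and myoid lists and down for the endothelial list, against the sign of their medians. The immediate-early list had a mean of 0.0089, opposite in sign to its median. Ribosomal and immediate-early genes were called in opposite directions by which deleted library was left out: without deleted replicate 1 the medians were -0.059 and -0.19, and without deleted replicate 2 they were 0.13 and 0.20. With 1 library left out, the medians of the DNA replication, retinoic acid, interferon, Sertoli, myoid and endothelial lists changed sign too, uncalled, and lay farthest from 0 for myoid genes (0.13 without control replicate 2) and Sertoli cells (-0.096 without deleted replicate 1). DNA replication genes passed without deleted replicate 2 (median 0.11, camera adjusted p = 0.00286), and with all libraries had a camera adjusted p of 0.0626 (0.972 with an estimated correlation).

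The second comparison asked which genes changed with the 23KRA allele. None of 14208 genes tested passed, and the genes of smallest p are given as values. Slc25a31, a testis adenine nucleotide carrier of mitochondria, was at 107 ± 8.47 CPM in wild type and 134 ± 8.91 CPM in homozygotes (SD, n = 5 each; log2 fold change 0.32, SE 0.089). Hnrnpd, an RNA-binding protein gene, was at 261 ± 33.7 and 208 ± 11.6 CPM (-0.33, SE 0.088), and Med17, a Mediator subunit gene, at 82.6 ± 4.72 and 102 ± 5.36 CPM (0.31, SE 0.092). Galnt11, a glycosyltransferase gene, had log2 fold change 0.44 (SE 0.13), Mob1b, of the Hippo pathway, 0.49 (SE 0.14), the protease gene Adamts10 0.93 (SE 0.28) and the kinase gene Pskh1 0.65 (SE 0.20). The heat shock factor gene Hsf4 (0.228 ± 0.162 against 2.79 ± 2.06 CPM), Ano8 (4.73 ± 3.98 against 0.725 ± 0.694 CPM) and Tspan17 (2.14 ± 2.46 against 0.128 ± 0.161 CPM) had larger differences at low and variable levels. The smallest adjusted p of any gene was 1.00 to 2 decimals. By the edgeR test 432 genes had an unadjusted p under 0.05, where 710 were expected by chance, and DESeq2 (720 unadjusted) and limma-voom (537 unadjusted) called 0 genes as well. In simulated counts of this experiment the test recovered 29.6% of 1.5-fold and 43.6% of 2-fold changes over all genes, and 45.4% and 77.9% among genes of at least 10 CPM. Simulated libraries share no structure, and the edgeR test of the real ones was conservative, so recovery in real counts may be lower.

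By gene list, differentiating and undifferentiated spermatogonia genes did not pass in 23KRA homozygotes. Stra8 was at 726 ± 64.9 CPM in wild type and 666 ± 113 CPM in homozygotes and Tex14 at 440 ± 20.8 and 439 ± 22.5 CPM (SD, n = 5; 20 differentiating genes, 7 above 0, median log2 fold change -0.033). Uchl1 was at 299 against 293 CPM and Taf4b at 217 against 228 CPM (25 undifferentiated genes, 13 above 0, median 0.013, SD 0.35). Only 5 Hox genes were high enough to test (Hoxa4 at 3.46 ± 2.19 against 1.96 ± 1.83 CPM, Hoxd8 at 3.63 ± 3.63 against 2.68 ± 2.22 CPM; median -0.44), and the other Hox genes did not meet the count filter. The summed level of these 5 was 11.0 ± 3.95 CPM in wild type and 8.96 ± 1.54 CPM in homozygotes (SD, n = 5; exact two-sided permutation p = 0.413, adjusted p over 21 lists = 0.833). The Hox median was 0.28 without wild-type replicate 1 and -0.68 without wild-type replicate 3. The 25 other developmental transcription factors tested had a median of 0.031 (Tbx1 at 36.3 against 41.6 CPM, Lhx6 at 17.3 against 13.9 CPM). PRC1 subunits (22 genes, median -0.0062; Scml2 at 479 against 514 CPM, Bmi1 at 182 against 200 CPM) and PRC2 subunits (13 genes, median 0.0025, with camera pointing down; Jarid2 at 340 against 319 CPM, Rbbp7 at 327 against 329 CPM) did not pass. With 1 library left out, the medians of the PRC1, PRC2, developmental factor and undifferentiated lists changed sign, at most to 0.036, -0.014, -0.056 and -0.065.

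The limma camera test called 2 of 21 lists in the 23KRA experiment. Ribosomal protein genes were higher (53 of 56 above 0, median log2 fold change 0.069; limma camera adjusted p = 1.19e-04; adjusted p = 0.865 with an estimated correlation), with Rpsa at 1572 ± 177 against 1621 ± 136 CPM and Rplp2 at 1176 ± 104 against 1178 ± 92.8 CPM (SD, n = 5). Spermatid transcripts were lower (21 of 24 below 0, median -0.32; limma camera adjusted p = 1.71e-04; adjusted p = 0.782 with an estimated correlation), with Prm2 at 315 ± 142 against 249 ± 136 CPM and Tnp1 at 117 ± 46.5 against 116 ± 64.2 CPM (SD, n = 5). The summed spermatid level was 1279 ± 522 CPM in wild type and 1055 ± 588 CPM in homozygotes (SD, n = 5 each), and the groups overlapped (exact two-sided permutation p = 0.492; adjusted p over 21 lists = 0.833). Neither list passed with an estimated correlation. The spermatid median was -0.079 without wild-type replicate 5 and -0.082 without homozygous replicate 2, and the call was lost in both cases. It was -0.20 without homozygous replicate 3, -0.51 without wild-type replicate 2 and -0.62 without homozygous replicate 5. The ribosomal call was lost without wild-type replicate 1, wild-type replicate 5 or homozygous replicate 2, at medians of 0.022, 0.043 and 0.045. The ribosomal median was 0.040 without homozygous replicate 4, 0.12 without wild-type replicate 2, 0.11 without wild-type replicate 4 and 0.11 without homozygous replicate 5.

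**Figure D4:**
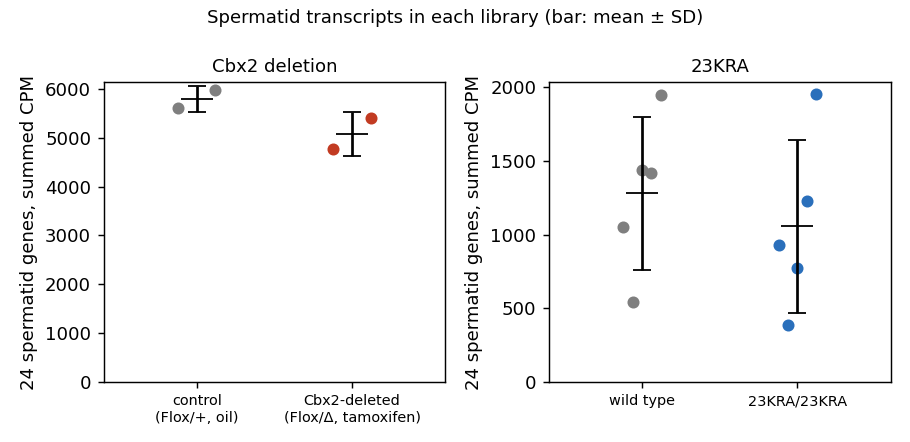
Summed CPM of the 24 spermatid genes (vertical, a separate scale per panel) in each library (points), with group mean and SD (bars), for the deletion experiment on the left and 23KRA on the right. The deleted libraries are below both controls, and the 23KRA groups overlap, with values from 387 to 1956 CPM.

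The other lists did not pass in 23KRA. Median log2 fold changes were 0.038 for 37 genes of meiotic prophase (Smc1b at 1506 against 1533 CPM, Tex15 at 1386 against 1522 CPM), 0.046 for 48 DNA replication genes (Lig1 at 561 against 543 CPM, Pole at 531 against 500 CPM) and 0.017 for 30 genes of the G2/M phase (Cenpf at 2937 against 2959 CPM, Mki67 at 2296 against 2322 CPM). For 8 CDK inhibitors the median was 0.13 (Cdkn2a at 59.2 against 70.7 CPM, Cdkn3 at 25.2 against 26.4 CPM), for 24 p53 targets 0.011 (Mdm2 at 175 against 178 CPM, Xpc at 131 against 123 CPM) and for 13 genes of the retinoic acid response -0.014 (Crabp1 at 121 against 118 CPM). For 21 immediate-early genes it was -0.19 (Jund at 103 against 104 CPM, Klf4 at 69.9 against 59.5 CPM; 0.049 without wild-type replicate 3) and for 10 interferon response genes 0.12 (Irf9 at 21.4 against 23.9 CPM). Among markers of other cells, the median was 0.013 for 15 Sertoli cell genes (Ctsl at 85.5 against 84.6 CPM, Clu at 32.3 against 32.6 CPM), -0.087 for 7 myoid genes (Mylk at 64.1 against 60.4 CPM, Actg2 at 13.8 against 11.3 CPM), -0.39 for 5 endothelial genes (Egfl7 with log2 fold change 0.16, Vwf at 2.40 against 0.936 CPM). The endothelial median was -0.91, -0.86 and -0.73 without homozygous replicates 5, 4 and 2, and -0.61 without wild-type replicate 2. All 7 macrophage and leukocyte genes tested were below 0 (limma camera adjusted p = 0.0932; H2-Ab1 at 18.1 ± 17.3 against 10.3 ± 3.68 CPM, Apoe at 15.9 against 11.2 CPM). Their list passed without wild-type replicate 5 (median -1.33), homozygous replicate 3 (-1.16) or homozygous replicate 4 (-1.17), and had a median of -0.025 without wild-type replicate 3. Camera pointed down for the p53 and Sertoli lists and up for the retinoic acid list, against the sign of their medians. Means were opposite in sign to medians for CDK inhibitors (-0.069) and myoid genes (0.0078). With 1 library left out, medians changed sign for CDK inhibitors (-0.069 without homozygous replicate 3), interferon response genes (-0.035 without wild-type replicate 5) and Sertoli cells (at most to -0.16, without wild-type replicate 2). They also did for the meiotic prophase, G2/M, p53, retinoic acid and myoid lists, and none of these was called. Of the 5 Leydig list genes tested, 4 were above 0 (median 0.43), among them Star at 11.9 against 12.3 CPM. This median was 0.19 without wild-type replicate 5, 0.21 without homozygous replicate 4 and 0.69 without wild-type replicate 4. Scarb1, a lipoprotein receptor gene, fell when adjusted over the list alone, from 61.9 ± 8.40 to 46.4 ± 6.82 CPM (SD, n = 5; log2 fold change -0.41, SE 0.13; edgeR adjusted p over the list alone = 0.0283), while no gene of the list passed over all genes tested. The summed Leydig level was 79.1 ± 8.41 and 67.1 ± 5.50 CPM (SD, n = 5; exact two-sided permutation p = 0.0159, adjusted p over 21 lists = 0.333). Most of this sum was Scarb1, so its fall was that of 1 gene, while the other 4 genes were above 0.

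The deletion and the 23KRA allele were then compared with each other. No gene passed in both experiments, and none of 13979 genes tested in both passed for a difference between the effects of the deletion and of 23KRA. The edgeR interaction test, in 1 fit of all 14 libraries, had 44 genes at an unadjusted p under 0.05, and limma-voom also called 0, with 207 unadjusted. Chance would give a share of 0.05, so both tests were conservative. In simulated counts the edgeR contrast recovered 27 of 39 genes changed 4-fold in the deletion. The lack of calls therefore does not show that the 2 effects agree. Across these genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.074 and Spearman rho = 0.14. Among the 8426 genes with at least 10 CPM in both, r was 0.21 and rho 0.23, and rho was 0.042 without deleted replicate 1, 0.12 without control replicate 2, 0.13 without wild-type replicate 5, and 0.15 without wild-type replicate 1 or homozygous replicate 2. The genes with an unadjusted p under 0.05 in both numbered 12, where 19.1 were expected from independent lists. Of these, 7 were higher in both, 4 lower in both and 1 opposite. The 100 genes with the smallest p among risers of the deletion had a median log2 fold change of 0.051 in 23KRA (58 above 0; camera p = 0.111, and p = 0.319 with an estimated correlation). The 100 such fallers had a median of -0.099 (41 above 0; camera p = 0.0426, adjusted p = 0.0852 over the 2 sets, and p = 0.450 with an estimated correlation). The risers passed without wild-type replicate 3 (0.098) or homozygous replicate 5 (0.076) and had a median of -0.016 without wild-type replicate 5, and the fallers passed without wild-type replicate 2 (-0.13) or homozygous replicate 5 (-0.14). The library kit differed between the experiments, so levels were compared only within each.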

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

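Among the tests in this part, those of depth, of the Leydig cell genes and of tamoxifen were chosen only after the result was seen, and the test of lists for a difference between the experiments was not among the tests fixed before the data were examined.

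In the 23KRA experiment, 72 groups of 5 values were checked for a library far from the others of its group. Of these, 6 had one, and 3.6 are expected by chance if values are normally distributed. The values were unlogged and included genes picked for their small p, among them Ano8, Tspan17 and Pskh1, so 3.6 is only a rough reference. Wild-type replicate 3 had a summed macrophage and leukocyte level of 174 CPM, against 17.9 to 49.9 CPM in the other wild-type libraries. Homozygous replicate 1 had a summed Hox level of 11.6 CPM, against 7.86 to 8.93 CPM. Homozygous replicate 3 had a summed interferon response level of 109 CPM, against 84.8 to 88.7 CPM, and Ano8 at 1.93 CPM, against 0.197 to 0.595 CPM. Wild-type replicate 2 had Tspan17 at 6.52 CPM, against 0.643 to 1.36 CPM, and Pskh1 at 25.6 CPM, against 14.5 to 17.2 CPM.

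A camera test of the interaction called a difference between the effects of the deletion and of 23KRA for 2 of 21 lists. For the 7 macrophage and leukocyte genes tested in both, the median difference of log2 fold change, deletion minus 23KRA, was 1.38 (camera adjusted p = 0.0171; adjusted p = 0.791 with an estimated correlation). For 56 ribosomal protein genes it was -0.056 (camera adjusted p = 0.0371; adjusted p = 0.896 with an estimated correlation). Summed macrophage levels were highest in deleted replicate 1 (145 CPM) and, among the 10 libraries of 23KRA, in wild-type replicate 3 (174 CPM). Without deleted replicate 1 the macrophage median of the deletion changed sign, and without wild-type replicate 3 that of 23KRA nearly vanished. The interaction test was not repeated with a library left out. Ribosomal medians were positive in both experiments (0.039 in the deletion and 0.069 in 23KRA).

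Replicates of the 23KRA experiment differed more than those of the deletion. Depth as the whole cause is argued against: over 13160 genes of at least 1 CPM in both, the coefficient of variation within groups, counting noise included, was 0.320 of the 23KRA value in the deletion libraries and 0.348 after thinning them to the median 23KRA total. Variation between animals as the whole cause is argued against by a variance-to-mean ratio at 5 to 20 counts that was 13.9 times what genes over 1000 counts predict, if low and high genes vary alike between animals. A small number of RNA molecules behind each amplified library may contribute, since that ratio was 15.5 in 23KRA, but the bound set for the deletion libraries, under 2, was missed at 2.25. This explanation and the change of kit stay open.

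Cyp17a1 was lower in both deleted animals. A smaller share of Leydig cells in the sort, as the whole cause, would lower the other genes used mainly in these cells by about as much, and their weighted mean log2 fold change of -0.18 (SE 0.31, widened for the spread between them) lay 4.11 SE above that of Cyp17a1 (2.95 to 4.09 with each library left out). Cyp17a1 had the smallest p of all genes tested, so its fall and this distance are likely overstated. The distance alone does not exclude a loss of Leydig cells as the whole cause. These 6 genes did not share 1 shift (chi-square test of heterogeneity, Q = 26.5 on 5 degrees of freedom, p = 7.14e-05). Insl3 fell about as far (-1.79), and Hsd17b3 (-0.53), Hsd3b1 (-0.37) and Cyp11a1 (-0.29) were lower by less. Hsd3b6 (0.25) and Lhcgr (1.48) were higher, Lhcgr at only 0.213 and 0.477 CPM in controls and 0.738 and 1.22 CPM in deleted animals. A smaller loss of Leydig cells as a part of the fall stays open. The Leydig list genes other than Scarb1 were at most 6.07 CPM in either group of the deletion, and the sort was for c-KIT, which Leydig cells can carry. Tamoxifen, the induced deletion and the Δ allele that deleted animals carried in place of + cannot be told apart here. The Rosa26-CreERT2 driver does not restrict the deletion to germ cells. Of the libraries, 0 tamoxifen-injected ones had the control genotype and no oil-injected one was Flox/Δ, so all of these stay open as explanations.

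The fold changes of the deletion and of 23KRA were correlated across genes of at least 10 CPM (Spearman rho 0.23 on differences of mean log2 CPM). Chance could not be excluded: 27 of 100 splits of the 23KRA libraries gave a rho as large in size, and the highest other was 0.395. These splits ignore replicate numbers, so they are a fair reference only if libraries of the same number share no preparation. A different amount of spermatid RNA was not decided by adjusting for each gene's slope on spermatid level, which kept 0.898 of the rho (0.786 to 1.21 with each library left out). That slope was estimated with error from the 10 libraries of 23KRA. It correlated only weakly with the fold changes (Spearman rho -0.22 with the deletion and -0.14 with 23KRA), so the adjustment could remove little, and this explanation stays open. Adjusting for GC content, length and expression kept 0.754 of the rho (0.601 to 1.24 with each library left out), which leaves these open too. No biological explanation is called for while chance stays open.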

How the results depend on the processing

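The limma-voom fit with quality weights and the 23KRA fit without the 2 libraries with the fewest genes detected were chosen after seeing the data. Of the alternatives of the main counts and values, 124 kept their side of the threshold or, for counts, stayed within 1.5 times, 18 moved and 5 newly passed. By the call alone, 280 alternatives of named genes kept their side, 5 no longer passed and 16 newly passed. Among lists these were 446, 24 and 9, with 4 reversed, and medians on the same side still changed in size and some in sign. The 2 genes of the deletion became 8 without the filter, 1 with a filter at 5 CPM (Cyp17a1 was not tested), 1 with DESeq2, 1 with limma-voom, 0 with quality weights, 62 (33 higher, 29 lower) with the replicate block and 2 to 73 with each library left out. The adjusted p of Cyp17a1 ranged from 3.25e-11 to 0.0656 over its alternatives and that of Dcn from 8.08e-17 to 1. The lists called in the deletion fell from 5 to 0 with an estimated correlation and to 0 with fry, became 6 with the replicate block, which added DNA replication (camera adjusted p = 0.0345), and ranged from 2 to 7 with each library left out. With a library left out, the macrophage median ranged from -0.16 to 0.82, the immediate-early median of the deletion from -0.19 to 0.20 and the ribosomal median of the deletion from -0.059 to 0.13. The 0 genes of 23KRA became 2 (Gm12260 and Pmfbp1, named after their values were seen) with the replicate block and stayed at 0 in the other alternatives, including without the 2 libraries with the fewest genes detected, where 3 lists passed. The lists called in 23KRA fell from 2 to 0 with an estimated correlation and to 0 with fry, and ranged from 0 to 3 with each library left out. The Pearson correlation of fold changes was 0.21 at 10 CPM and above, against 0.074 over all genes (jackknife error 0.098), and the Spearman rho of 0.23 at 10 CPM and above had a jackknife error of 0.25. The deletion's risers had a median of -0.016 to 0.098 in 23KRA with a library left out and its fallers -0.14 to -0.023, and -0.092 with the replicate block, past the threshold. The cause was not tested for any of these except where fewer genes or libraries entered the fit; with 1 library left in an arm, it is assumed to vary like the other group. Replicate numbers were not taken as pairing, since the labels state none. The correlation of deviations was 0.16 in the deletion, where both numbers share 1 value, and -0.011 to 0.22 in 23KRA. There, 2 of 5 were over 0.1, and 7 of 10 libraries matched their own number best, more than random matching would give. Summed ribosomal and retinoic acid levels, picked after they were seen, followed the same order of replicate numbers in both genotypes. Not every list did, CDK inhibitors among those that did not. Spermatid levels differed in order, but replicate 5 was highest (1949 CPM in wild type, 1956 CPM in homozygotes) and replicate 2 lowest (540 and 387 CPM) in both. Ribosomal levels ran from 25856 to 19812 CPM in wild type and from 26477 to 21406 CPM in homozygotes. A preparation shared by number cannot be excluded, and the unpaired tests and permutations would ignore it. Low genes were measured poorly in 23KRA, where 562 to 1889 genes per library had 0 counts while another library had over 20, against 0 to 3 in the deletion. This count also rises with the number of libraries, 10 in 23KRA and 4 in the deletion, and a difference in depth was not shown to cause it.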

Other observations

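The split tests in this part were written before their results were seen, and the values of the second paragraph were chosen after. The number of genes past the threshold in 23KRA was 0, so all 100 splits of the 10 libraries, drawn from 126, gave as many, and the highest other split gave 105 genes. Of the other 99 splits, 3 called any gene. The split with 105 genes, against 0 in the real one, may point to a structure of the libraries, such as one shared by replicate number, which was not tested. For gene lists chance could not be excluded: 70 of 100 splits gave at least the 2 lists that camera called, with a highest of 7. The splits ignore replicate numbers, while the real grouping holds each number once per genotype. They are a fair reference only if libraries of the same number share no preparation. The spermatid list was called in 67 and the ribosomal list in 64 of the 100 splits, the real one included.

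Summed spermatid levels in 23KRA were 540 to 1949 CPM in wild type and 387 to 1956 CPM in homozygotes. Rn45s, a ribosomal RNA precursor, or Rpph1, the RNA of ribonuclease P, was the highest gene in each 23KRA library at 2.43% to 3.31% of counts, while Lars2 led each deletion library at 0.670% to 0.948%.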
